A study of Rattus norvegicus with 6 samples.

How the data were processed

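Total RNA of rat flexor digitorum longus muscle was depleted of ribosomal RNA and sequenced, per the labels' protocols, in 6 libraries: 3 of control muscle at 0 h and 3 of muscle at 18 h after ACS was induced. Groups and replicate numbers came from the sample titles. The treatment field of the labels reads ACS for all 6 libraries, so it did not separate the groups. Whether libraries of different groups share a rat is not given in the sources used here.

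The deposited table gives whole-number read counts per gene and FPKM values (fragments scaled by gene length and library size) for 30957 Ensembl genes. HISAT2 2.0.4, StringTie 1.3.0 and the rat build Rnor 6.0 are named, per the submitters' processing notes. The tool that made the counts, its strand setting and its treatment of reads that match several places are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner may therefore not be told apart, and near-identical copies (metallothioneins, haemoglobins, Hspa1a and Hspa1b, ferritins, and genes with processed pseudogenes such as Hspa8 and Txn1) are uncertain. The authors' FPKM equalled the count divided by 1 gene length and the column total in all 17185 genes that could be checked, to within 0.1%. Counts were used for the main tests and FPKM for an alternative.

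Library totals lay between 14340865 and 21003928 counts. At this depth a count of 0 in all control libraries was treated as a floor of 3 counts over the group, and ratios with 1 to 3 control counts carry exact binomial intervals of 95%, which cover counting error only. No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom over genes with at least 10 counts lay between 40.7 and 777, so none was treated as a duplicate.

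Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 12873. Normalization factors were TMM, and the test was edgeR's quasi-likelihood F test of group with Benjamini-Hochberg adjustment and a threshold of 0.05, with no fold limit. The common biological coefficient of variation was 0.381. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled, with the SD over 3 libraries. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.

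Before the data were examined, 28 gene lists were fixed with 415 entries (407 different symbols), covering cell death, stress, inflammation, matrix, muscle fibre and metabolic genes and markers of other cell types. Of these 402 entries were matched to the table by symbol, 3 of them through an older symbol in the RefSeq gene table of a later rat assembly; 13 were not matched, and 4 symbols with several rows took the row with most counts. Some genes stand in more than 1 list, such as Hmox1 and Gclc. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Of the 18 lists past the camera threshold, 0 passed with an estimated correlation. That setting also tests with the few degrees of freedom that 6 libraries leave. A list lost there is therefore not shown to be unchanged, nor its genes to be correlated.

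The genes named were also fixed before the data were examined: the 3 title genes; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 10 CPM in the higher group, full separation of the groups and a gene symbol; and in each list up to 3 members with the smallest adjusted p, or the most abundant member where none passed. Genes named outside the rule are said to be so, and 1 gene outside it is not reported here.

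On simulated counts for ACS against control, drawn for 12873 genes from the real means, library sizes and dispersions with 4 sets of 50 changed genes, edgeR recovered 2% of genes changed 2-fold, 54% of those changed 4-fold, 84% at 8-fold and 98% at 16-fold. Of its 129 calls 7.75% were false. DESeq2 made 193 calls with 25.4% false and limma-voom 130 with 8.46% false. With quality weights limma-voom made 129 with 7.75% false, and limma on FPKM 117 with 8.55% false. The simulation held as many increases as decreases and no library that stood apart, as ACS replicate 1 did in the real data. There limma-voom called 333 genes, and 1415 with quality weights. The simulated shares therefore need not hold for the real data.

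The alternatives covered normalization (DESeq2 size factors, library totals, TMM without haemoglobin and mitochondrial genes), tests (DESeq2, limma-voom, limma on log2(FPKM + 1) for genes at 1 or more FPKM in at least 3 libraries), filters (none; 50 counts in every library of a group), a replicate block, a 2-fold limit, the libraries whose description holds "ji", and leaving out each library in turn. Quality weights in limma-voom, and TMM without haemoglobin and mitochondrial genes together with leaving out ACS replicate 1, were added after seeing the data.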

Results

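RNA was sequenced from the flexor digitorum longus, a hind-limb muscle that flexes the toes, of Sprague-Dawley rats. The comparison set muscle at 18 h of acute osteofascial compartment syndrome (ACS), in which raised pressure inside a closed muscle compartment limits its blood supply, against control muscle at 0 h. ACS was induced with a tight elastic loop around the knee. Each group held 3 libraries. The series title names Acsl4, Gpx4 and Ptgs2 and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, so the comparison asks how these genes and the rest of the transcriptome differ between ACS and control muscle. The labels do not say whether the libraries of a group came from separate rats, so p-values measure only the spread between these samples, which may be technical.

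The control libraries held 18843880, 18450886 and 21003928 counts and the ACS libraries 14340865, 19376341 and 18916880. Genes of the mitochondrial chromosome took 8.60%, 8.38% and 7.52% of the counts in control muscle. In ACS replicates 1, 2 and 3 they took 43.4%, 4.82% and 5.33%, so that ACS replicate 1 stood apart. Haemoglobin genes took 0.159% ± 0.0724 (SD, n = 3) of the counts in control and 0.721% ± 0.491 (SD, n = 3) in ACS muscle, with 1.26%, 0.293% and 0.613% in ACS replicates 1, 2 and 3. The first principal component of log2 CPM (counts scaled by library size) held 59.94% of the variance. It placed the control libraries between -55.5 and -48.18 and the ACS libraries at 112.4, 37.1 and 9.469. Pairs of control libraries correlated at 0.968 to 0.973 across genes and pairs of ACS libraries at 0.877 to 0.945 (Pearson), where genes are not independent replicates.

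**Figure D1:**
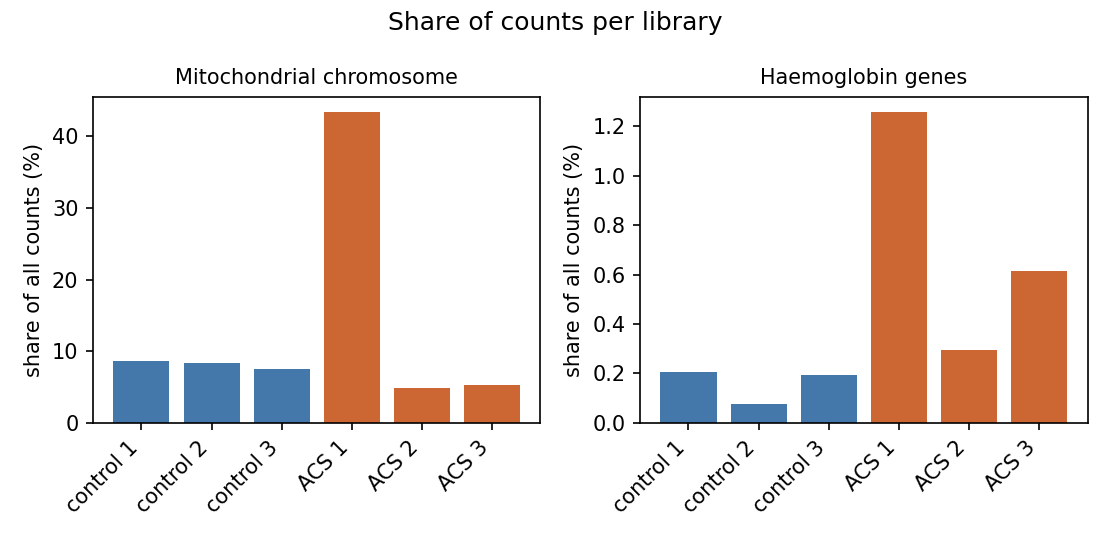
Share of all counts, in percent on the vertical axis, taken by genes of the mitochondrial chromosome (left) and by haemoglobin genes (right), with 1 bar per library on the horizontal axis. ACS replicate 1 reached 43.4% for the mitochondrial chromosome, while the other 5 libraries lay between 4.82% and 8.60%.

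Genes that rose in ACS muscle at 18 h included metallothioneins, small metal-binding proteins: Mt1 on chromosome 17 went from 0.977 ± 0.239 to 812 ± 551 CPM (SD, n = 3 each), a log2 fold change of 9.69 (SE 0.870). The cytokine Il6 rose from 0.178 ± 0.170 to 55.6 ± 80.0 CPM and the transcription factor Fosl1 from 0.0806 ± 0.140 to 36.5 ± 54.2 CPM. ACS replicate 1 held most of both, and without it their log2 fold changes were 5.74 for Il6 and 5.97 for Fosl1, against 8.28 and 8.76 with all libraries. Fosl1 was at 8.17, 12.35 and 8.09 without control replicates 1, 2 and 3, and Il6 at 8.31, 9.08 and 7.60. Among genes that fell, the homeobox factor Six4 went from 115 ± 7.75 to 27.6 ± 5.42 CPM and Idh1, the cytosolic isocitrate dehydrogenase, from 21.4 ± 3.33 to 5.15 ± 2.53 CPM.

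Of 12873 genes tested with edgeR's quasi-likelihood test, 442 were higher and 91 lower in ACS muscle at an adjusted p under 0.05. All 533 differed by at least 2-fold and had every ACS library on one side of every control library. Of all tested genes 31.5% were separated in this way, against the 10% that chance gives for 3 libraries against 3. The largest increases by the naming rule were Cxcl6, Mmp3, Mt1 on chromosome 17, Fosl1, Mt1 on chromosome 19, Mt2A, Mt1m, Il6, Slpi and Trem1. Cxcl6, a neutrophil-attracting chemokine, had no count in control muscle and 1117 counts in ACS muscle, at least 507-fold higher against a floor of 3 counts over the control group (adjusted p = 0.0489). Its ACS libraries were at 88.4, 6.74 and 2.29 CPM. The bound was at least 100.4-fold without replicate 1, at least 751-fold without replicate 2 and at least 779-fold without replicate 3. With a control left out it was at least 348-fold, 347-fold and 319-fold. It did not pass without replicate 2 (adjusted p = 0.0628). Mmp3, a matrix-degrading protease, had 1 control count and a count ratio of 961, with a 95% counting interval of 172 to 38015 (adjusted p = 0.0352). Its ACS libraries were at 55.5, 4.94 and 0.949 CPM, and without replicate 1 the ratio was 198 (34.8 to 7883). It was 1395 and 1496 without ACS replicates 2 and 3, and 660, at least 219 and 605 without control replicates 1, 2 and 3. Mt2A and Mt1m rose by log2 fold changes of 8.44 (SE 0.973) and 8.38 (SE 1.19). Control replicate 3 was the highest control for both, and without it they were at 9.12 and 10.19 and neither passed (adjusted p = 0.0521 for each). The Mt1, Mt2A and Mt1m loci are near-identical copies, so the split of reads among them is uncertain. The largest decreases were in Zc2hc1c, Ppp1r27, Zfp395, Galnt5, Lmod1, Sbk2, Cxxc5, Pcdh12, Idh1 and Six4, with log2 fold changes from -3.02 (SE 0.444) in Zc2hc1c to -2.05 (SE 0.255) in Six4. Without ACS replicate 2 Galnt5, Lmod1, Sbk2 and Pcdh12 did not pass (adjusted p from 0.0670 to 0.111), nor Sbk2 without replicate 1 (adjusted p = 0.0555). Sbk2 was at -2.15, or -1.49 without control replicate 1.

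Scaling by library totals gave 345 higher and 228 lower genes with a median log2 fold change of -0.32 over all genes. Limma on log2(FPKM + 1) gave 249 higher and 268 lower with a median of -0.30. The split of 82.9% higher moved to 60.2% and 48.2%. Leaving out any 1 control library left 0 genes past the edgeR threshold, in any list or outside the lists, with 2075, 2063 and 2289 genes at an unadjusted p under 0.05. Without ACS replicates 1, 2 and 3 the counts were 656 higher and 222 lower, 282 and 17, and 1286 and 398. A term for the 2 libraries described with "ji", 1 in each group, gave 248 higher and 32 lower genes, and leaving both out gave 171 and 30. DESeq2 called 1320 genes higher and 429 lower and limma-voom 262 and 71.

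Of the genes named in the title, Acsl4 measured 35.1 ± 7.36 CPM in control and 81.0 ± 25.2 CPM in ACS muscle (SD, n = 3 each). Acsl4 is a long-chain acyl-CoA synthetase that activates polyunsaturated fatty acids by joining them to coenzyme A. Ptgs2, which encodes the inducible cyclooxygenase, measured 1.33 ± 0.772 and 27.2 ± 35.7 CPM, with 68.4, 7.20 and 6.03 CPM in ACS replicates 1, 2 and 3. Both were higher in every ACS library than in every control library. Gpx4, the glutathione peroxidase that reduces lipid hydroperoxides, measured 223 ± 46.8 and 159 ± 87.5 CPM, and its groups overlapped.

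The log2 fold change was 1.20 for Acsl4 (SE 0.305, adjusted p = 0.0603 over all genes) and 4.35 for Ptgs2 (SE 1.05, adjusted p = 0.0553), so neither passed the edgeR threshold. For Gpx4 it was -0.49 (SE 0.436, adjusted p = 0.529), with a 95% interval from -1.48 to 0.50. In edgeR, adjusted over the list alone (the 3 title genes), adjusted p was 0.00550 for Acsl4, 0.00550 for Ptgs2 and 0.293 for Gpx4. The study names these genes in its title, so this is not independent evidence of their direction. Two-sided exact permutation tests gave p = 0.1 for Acsl4 and Ptgs2, the smallest that 3 libraries against 3 allow, and p = 0.4 for Gpx4. Without ACS replicate 1 the log2 fold change of Ptgs2 was 2.31 (adjusted p = 0.0348), that of Acsl4 0.93 (adjusted p = 0.0613) and that of Gpx4 -0.13 (adjusted p = 0.827). Without ACS replicate 3 Ptgs2 was at 4.82 (adjusted p = 0.0235) and Acsl4 at 1.37 (adjusted p = 0.0287), and without ACS replicate 2 Gpx4 was at -0.96. Over all alternatives adjusted p lay between 0.00915 and 0.255 for Acsl4 (past the threshold in 3 of 19), between 0.0124 and 0.198 for Ptgs2 (9 of 18) and between 0.267 and 0.833 for Gpx4 (0 of 19). Acsl4 (ENSRNOG00000019180) spans positions 113596239 to 113659944 of chromosome X, Gpx4 (ENSRNOG00000013604) 12516357 to 12519154 of chromosome 7 and Ptgs2 (ENSRNOG00000002525) 67351087 to 67359335 of chromosome 13, on the rat build Rnor 6.0.

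**Figure D2:**
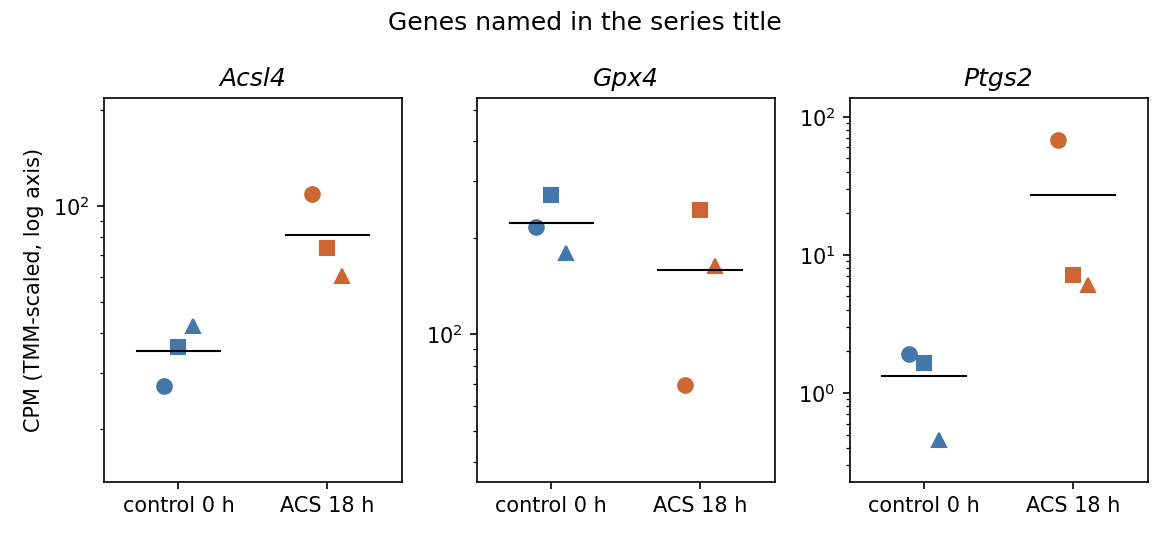
Abundance of Acsl4, Gpx4 and Ptgs2 in CPM on a log axis, by group on the horizontal axis; each point is a library (circle, square and triangle for replicates 1, 2 and 3) and the line is the group mean. Acsl4 and Ptgs2 lay above every control library in all 3 ACS libraries, and Gpx4 overlapped between groups.

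Among 21 ferroptosis drivers and markers, 2 rose and none fell. Hmox1, the haem-degrading oxygenase, went from 1.38 ± 0.407 to 145 ± 97.3 CPM (log2 fold change 6.71, SE 0.663, adjusted p = 0.00820; 6.12 without ACS replicate 1), and Sat1, which acetylates polyamines, from 13.6 ± 7.45 to 73.5 ± 24.9 CPM (2.43, SE 0.440). Of 19 tested ferroptosis suppressors, 2 rose: Ftl1, the ferritin light chain that stores iron, from 6.95 ± 0.274 to 22.8 ± 4.49 CPM, and Gclc, the catalytic subunit for glutathione synthesis, from 14.1 ± 3.09 to 64.3 ± 44.3 CPM (log2 fold change 2.18, or 1.47 without ACS replicate 1). Of 17 oxidative stress and metallothionein genes, 6 rose, led by Mt1, Hmox1 and Mt2A.

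In these lists, adjusted over the list alone, 4 drivers, 5 suppressors and 8 oxidative stress genes were higher and none lower. The camera set test, which compares a list with all other genes, put the drivers (adjusted p = 0.00928), the suppressors (adjusted p = 0.00994) and the oxidative stress list (adjusted p = 1.75e-08) upward, and each had adjusted p = 0.26 with an estimated correlation. Members higher numbered 3, 3 and 8 without ACS replicate 1, 1, 1 and 5 without replicate 2, 5, 6 and 9 without replicate 3 (with 1 driver lower), and 0 without any 1 control library. With the term for the "ji" libraries 3 drivers, 2 suppressors and 6 oxidative stress genes were higher, and without both libraries 1, 0 and 5. Reads of Ftl1 can be shared with ferritin pseudogenes, so its level is uncertain.

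Of 9 tested neutrophil markers, 8 rose in ACS muscle. The list held 15 markers, and the filter left out the rest. Only 1 of the 9 reached 1 CPM in control muscle. Markers could thus pass the filter through the ACS libraries, which made a high share of rises likely in advance. With no filter 9 of 13 were higher. Mmp8, the neutrophil collagenase, went from 0.254 ± 0.114 to 15.7 ± 14.5 CPM, S100a8, a calcium-binding protein of granulocytes, from 0.563 ± 0.519 to 18.8 ± 14.8 CPM, and Cxcr2, a receptor for neutrophil-attracting chemokines, from 0.290 ± 0.250 to 15.9 ± 18.9 CPM (log2 fold changes 5.89, SE 0.859; 5.01, SE 0.895; 5.70, SE 1.05). ACS replicate 1 was the highest for each, and without it their log2 fold changes were 4.85, 4.27 and 4.05 and the list's median was 4.24 against 5.70. Control replicate 3 was the highest control for S100a8 and Cxcr2, and without it they were at 6.05 and 6.64 and the list's median at 6.64. None of the 3 genes passed there (adjusted p = 0.0791, 0.0791 and 0.106). Trem1, an amplifier of myeloid inflammation, had 3 control counts and a count ratio of 185, with a counting interval of 62.8 to 899. Its ACS libraries were at 33.3, 1.23 and 1.51 CPM, and without replicate 1 the ratio was 29.8 (9.63 to 149). It was 292 and 275 without ACS replicates 2 and 3, and 380.3, 126 and 174 without control replicates 1, 2 and 3. Of 11 tested cytokines and chemokines, 4 rose: Csf3, Il6, Cxcl10 and, named after its values were seen, Cxcl1. The list held 16, and with no filter 13 of 16 were higher. Csf3, the granulocyte growth factor, had 1 control count and a count ratio of 275, with a counting interval of 48.8 to 10915, and a ratio of 95.5 (16.3 to 3858) without ACS replicate 3. It was 299 and 432 without ACS replicates 1 and 2, and at least 62.9, then 188 and 173, without control replicates 1, 2 and 3. Cxcl10 went from 0.206 ± 0.130 to 6.44 ± 6.66 CPM, with a log2 fold change of 4.93, or 3.67 without ACS replicate 1.

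Of 15 monocyte and macrophage markers, 2 rose: Gpnmb, a lysosomal glycoprotein, with a log2 fold change of 2.50 (SE 0.489), and Itgam, an integrin also carried by neutrophils, with 4.03 (SE 0.901), or 2.22 without ACS replicate 1. In the red cell and platelet list 2 of 10 rose, Alas2, the erythroid enzyme that starts haem synthesis (2.73, SE 0.586), and Hbb, a haemoglobin chain (2.19, SE 0.470) that shares reads with near-identical copies. The lymphocyte list of 14 had 1 tested member, Cd4, at 4.17 ± 0.838 and 3.36 ± 2.57 CPM (adjusted p = 0.734). A single gene does not report on lymphocytes as a set. For this list edgeR, limma-voom and limma on FPKM each called 0, with 1 member tested. DESeq2, run without that filter on all 14, also called 0. In edgeR 0 had an unadjusted p under 0.05. The level of Cd4 was lower on average, but turned higher without ACS replicate 3 (log2 fold change 0.0341, against -0.33 with all libraries and -1.12 without replicate 1), and the set test gave adjusted p = 0.64.

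Of these markers, adjusted over the list alone, 9 neutrophil, 10 cytokine, 11 macrophage and 10 red cell and platelet genes were higher. The set test put upward the neutrophil list (adjusted p = 1.35e-09; adjusted p = 0.26 with an estimated correlation), the cytokines (adjusted p = 1.20e-08; adjusted p = 0.26 with an estimated correlation), the macrophage list (adjusted p = 0.000244; adjusted p = 0.407 with an estimated correlation) and the red cell list (adjusted p = 6.60e-07; adjusted p = 0.301 with an estimated correlation). The haemoglobin share of the counts was also higher in ACS muscle, at 0.721% (0.453% without ACS replicate 1) against 0.159%. Neutrophil, cytokine, macrophage and red cell members higher numbered 8, 8, 3 and 2 without ACS replicate 1, 9, 7, 1 and 2 without replicate 2, 9, 10, 11 and 3 without replicate 3, and 0 without any 1 control library. With limma-voom 0 neutrophil, 0 cytokine and 0 macrophage members passed, against 8, 8 and 8 with DESeq2 (unadjusted p under 0.05 in edgeR for 9, 10 and 13). With the term for the "ji" libraries 2 neutrophil, 5 cytokine, 0 macrophage and 1 red cell members were higher. Without both "ji" libraries these were 0, 0, 1 and 0.

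**Figure D3:**
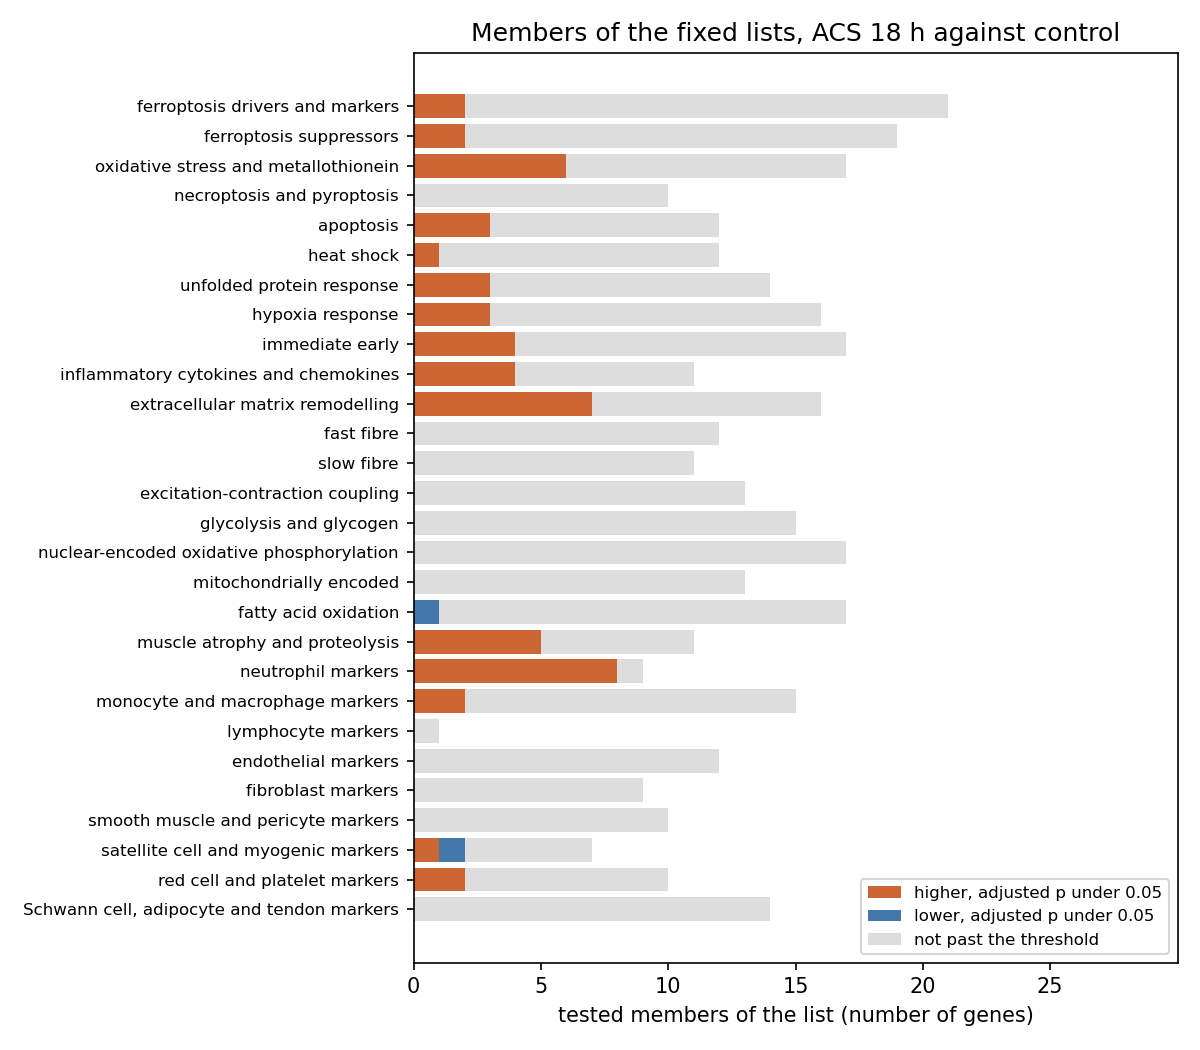
Number of tested members of each of the 28 fixed lists (horizontal axis) that were higher, lower or not past the adjusted threshold of edgeR. The neutrophil list has 8 of 9 tested members higher, and the extracellular matrix list 7 of 16.

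Of 16 genes of extracellular matrix remodelling, 7 rose. Adamts4, which cleaves aggrecan, went from 2.48 ± 1.14 to 54.0 ± 43.8 CPM (log2 fold change 4.44, SE 0.729), Has1, a hyaluronan synthase, from 0.286 ± 0.183 to 11.3 ± 9.97 CPM (5.29, SE 0.885) and Plau, the urokinase plasminogen activator, from 20.9 ± 5.24 to 87.5 ± 34.5 CPM (2.06, SE 0.348). Adamts4 was at 3.63 and Has1 at 4.35 without ACS replicate 1. By edgeR 13 were higher adjusted over the list alone, and 10, 6 and 13 passed without ACS replicates 1, 2 and 3 and 0 without any 1 control library. The set test put the list upward (adjusted p = 7.75e-10; adjusted p = 0.26 with an estimated correlation).

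The fixed lists of markers of resident non-muscle cells gave no member past the edgeR threshold. These lists do not cover all genes of such cells, and Lmod1 and Pcdh12, among the largest decreases, are in none of them. Among 9 fibroblast markers Col1a1, a chain of type I collagen, measured 357 ± 215 and 1310.0 ± 478 CPM (adjusted p = 0.0968, or 0.0466 without ACS replicate 1). No fibroblast marker passed in edgeR, limma-voom or limma on FPKM, while 2 did in DESeq2 and 6 had an unadjusted p under 0.05. Of the 9 markers 2 were higher adjusted over the list alone, and the set test was upward (adjusted p = 0.00514; adjusted p = 0.26 with an estimated correlation). Among 12 endothelial markers Cdh5 measured 86.3 ± 18.2 and 152 ± 107 CPM (log2 fold change 0.82, adjusted p = 0.320), and without ACS replicate 1 it was near control (0.0802, adjusted p = 0.895). The set test gave adjusted p = 0.994 (upward, but downward when scaled by library totals and without control replicate 2, ACS replicate 1 or ACS replicate 2, at 0.521, 0.124 and 0.829). EdgeR, limma-voom and limma on FPKM called 0 endothelial genes, DESeq2 called 1, and 2 had an unadjusted p under 0.05. Of 10 smooth muscle and pericyte markers 0 passed in edgeR, limma-voom or limma on FPKM, 1 was lower in DESeq2 and 2 had an unadjusted p under 0.05. Abcc9 measured 378 ± 27.1 and 330 ± 99.3 CPM, turning higher in ACS without replicate 1 (log2 fold change 0.0331), and the set test gave adjusted p = 0.0532 downward (0.0198 without control replicate 2 and 0.0338 without ACS replicate 1). In the Schwann cell, adipocyte and tendon list 0 of 14 passed in edgeR or limma-voom, 2 were higher and 1 lower in DESeq2, 1 was lower in limma on FPKM, and 6 had an unadjusted p under 0.05. Its most abundant member, Thbs4, measured 139 ± 54.8 and 339 ± 197 CPM (adjusted p = 0.163, or 0.0423 without ACS replicate 3), and the set test gave adjusted p = 0.275 (0.0125 without ACS replicate 3). With p adjusted over the list alone, 0 endothelial and 0 smooth muscle genes passed, and 2 were higher and 1 lower in the last list. Without ACS replicate 1, 1 fibroblast gene and 1 gene of the last list were higher and 2 endothelial genes lower. Without replicate 3, 2 endothelial genes and 5 of the last list were higher and 1 of the last lower.

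Of 16 hypoxia genes 3 rose: Adm, the vasodilator peptide adrenomedullin, from 2.76 ± 0.840 to 28.6 ± 14.3 CPM (log2 fold change 3.37, SE 0.453), Pfkfb3, an activator of glycolysis, from 159 ± 54.2 to 1338 ± 428 CPM (3.07, SE 0.414), and Hk2, a hexokinase, from 236 ± 47.0 to 1119 ± 295 CPM (2.24, SE 0.338). In the immediate early list 4 of 17 rose: Zfp36, which promotes mRNA decay, from 48.3 ± 6.66 to 432 ± 118 CPM, Myc from 3.0 ± 0.508 to 141 ± 111 CPM, Klf6 from 16.5 ± 4.80 to 60.1 ± 13.4 CPM, and Fosl1. Of 14 genes of the unfolded protein response 3 rose: Sesn2 (2.06, SE 0.431), the chaperone Hspa5 (2.43, SE 0.527) and its cofactor Dnajb9 (1.72, SE 0.375). Of 12 heat shock genes 1 rose, Bag3, a co-chaperone of damaged muscle proteins, from 143 ± 31.0 to 660.3 ± 388 CPM. The log2 fold change of Myc was 5.55, or 4.76 without ACS replicate 1, which also lowered Hspa5 to 1.57. That of Bag3 was 2.21, or 1.59 without ACS replicate 2.

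Of 12 apoptosis genes 3 rose: Bcl2l1, which inhibits cell death, from 17.0 ± 3.33 to 91.9 ± 43.8 CPM, and the death-promoting Pmaip1 and Bid by log2 fold changes of 3.86 (SE 0.653; 2.87 without ACS replicate 1) and 2.13 (SE 0.442; adjusted p = 0.0624 without ACS replicate 2). Of 10 necroptosis and pyroptosis genes none passed in edgeR, limma-voom or limma on FPKM, 4 were higher in DESeq2 and 5 had an unadjusted p under 0.05. Ripk1 measured 8.27 ± 1.01 and 32.4 ± 25.9 CPM (log2 fold change 1.97, adjusted p = 0.0817). It was at 1.14 without ACS replicate 1 (adjusted p = 0.113) and 2.39 without replicate 3 (adjusted p = 0.0120).

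For these lists, adjusted over the list alone, 5 hypoxia, 6 immediate early, 7 unfolded protein, 2 heat shock, 6 apoptosis and 4 necroptosis genes were higher. The set test put upward the hypoxia list (adjusted p = 0.000244; adjusted p = 0.26 with an estimated correlation), the immediate early list (adjusted p = 0.000244; adjusted p = 0.341 with an estimated correlation), the unfolded protein list (adjusted p = 0.000435; adjusted p = 0.26 with an estimated correlation), apoptosis (adjusted p = 0.0199; adjusted p = 0.373 with an estimated correlation) and necroptosis (adjusted p = 0.0452; adjusted p = 0.599 with an estimated correlation). For the immediate early list the set test gave adjusted p = 6.38e-08 without control replicate 2 and 0.0364 without control replicate 3. The median log2 CPM of that list was 4.72, 5.63 and 2.95 in control replicates 1, 2 and 3. In ACS replicates 1, 2 and 3 it was 6.63, 5.94 and 5.53, so the groups overlapped. Heat shock gave adjusted p = 0.0737 (0.0425 without ACS replicate 3). In the order hypoxia, immediate early, unfolded protein, heat shock, apoptosis and necroptosis, members higher numbered 3, 6, 4, 2, 3 and 1 without ACS replicate 1, 3, 4, 0, 0, 2 and 0 without replicate 2, 6, 4, 6, 2, 6 and 3 without replicate 3, and 0 in each without any 1 control library. In the same order they numbered 3, 4, 0, 0, 2 and 0 with the term for the "ji" libraries, and 1, 2, 1, 0, 1 and 0 without both. The necroptosis call of the set test was lost without control replicate 1 (0.0711), control replicate 3 (0.0524) and ACS replicate 1 (0.529).

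**Figure D4:**
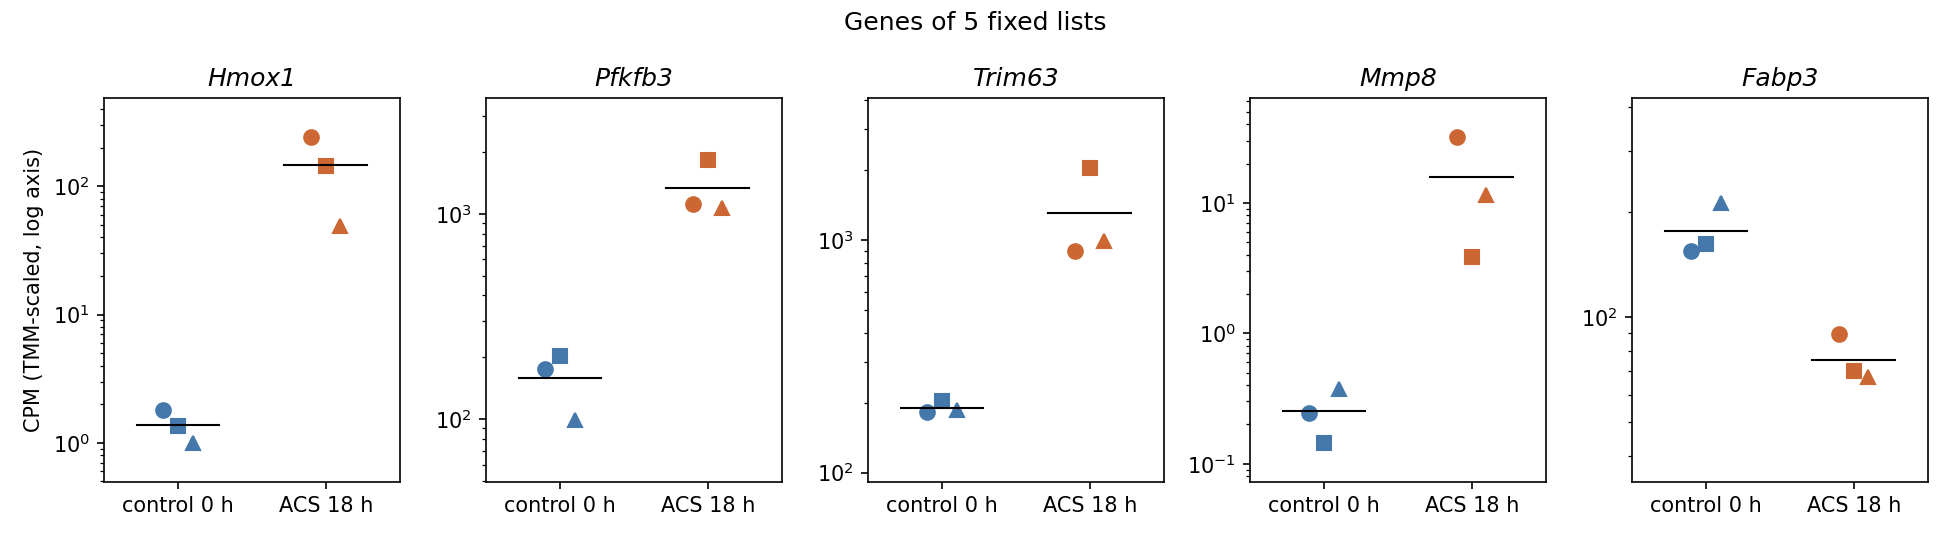
Abundance in CPM on a log axis of Hmox1, Pfkfb3, Trim63, Mmp8 and Fabp3, by group on the horizontal axis; each point is a library (circle, square and triangle for replicates 1, 2 and 3) and the line is the group mean. The first 4 genes lay above control in all 3 ACS libraries, and Fabp3 lay below, at 75.7 against 177 CPM on average.

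Of 11 genes of muscle atrophy and proteolysis, 5 rose in ACS muscle. Foxo1, a transcription factor of muscle wasting, went from 34.9 ± 13 to 381 ± 195 CPM (log2 fold change 3.45, SE 0.495), Trim63, the ubiquitin ligase MuRF1, from 190.5 ± 10.6 to 1313 ± 635 CPM (2.79, SE 0.403) and Gadd45a from 5.92 ± 0.559 to 192 ± 214 CPM (5.02, SE 0.847; 3.54 without ACS replicate 1). Mstn and Cdkn1a, named after their values were seen, also rose. Of the list 9 were higher adjusted over the list alone, and 7, 3 and 7 passed without ACS replicates 1, 2 and 3 and 0 without any 1 control library. The set test was upward (adjusted p = 1.75e-08; adjusted p = 0.26 with an estimated correlation).

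Fabp3, the fatty acid carrier of oxidative muscle, fell from 177 ± 31.2 to 75.7 ± 11.9 CPM (log2 fold change -1.22, SE 0.266, adjusted p = 0.0442), the 1 lower gene of 17 in the fatty acid oxidation list. Among myogenic markers Myf5 rose from 0.944 ± 0.377 to 4.34 ± 1.18 CPM while Myod1, another myogenic transcription factor, fell from 47.6 ± 5.70 to 19.6 ± 5.29 CPM, 1 higher and 1 lower of 7. No slow fibre, fast fibre, excitation-contraction coupling, glycolysis, nuclear-encoded oxidative phosphorylation or mitochondrially encoded gene passed in edgeR, limma-voom or limma on FPKM. DESeq2 called 3 slow fibre genes lower and 0 in the other 5 lists, and the genes at an unadjusted p under 0.05 were 4, 0, 0, 0, 1 and 3. Differences were smaller than the ACS spread for Myh1 (57520 ± 7887 and 63150 ± 34109 CPM, adjusted p = 0.904, opposite in sign when scaled by library totals and at -0.41 without ACS replicate 3), Ryr1 (7557 ± 805 and 7010 ± 3028 CPM) and Aldoa (9568 ± 1139 and 8074 ± 3972 CPM). Without ACS replicate 1 Ryr1 and Aldoa also turned sign, to log2 fold changes of 0.21 and 0.095. The row named Myh1 spans 134.4 kb and overlaps Myh8, so it may hold reads of neighbouring myosin genes. Myh7, the slow myosin heavy chain, measured 2033 ± 216 and 1231 ± 397 CPM (adjusted p = 0.253), Atp5b 2509 ± 212 and 1635 ± 589 CPM (adjusted p = 0.366) and Mt-co1 33868 ± 6824 and 53091 ± 52408 CPM (adjusted p = 0.613, opposite in sign with FPKM and at -0.57 without ACS replicate 1).

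The set test put downward the slow fibre list (adjusted p = 0.00146; adjusted p = 0.26 with an estimated correlation), nuclear-encoded oxidative phosphorylation (adjusted p = 0.00146; adjusted p = 0.535 with an estimated correlation) and fatty acid oxidation (adjusted p = 0.00297; adjusted p = 0.45 with an estimated correlation). Their median log2 fold changes were -0.72, -0.54 and -0.54. It gave adjusted p = 0.741 for the fast fibre list, whose median of 0.07 was opposite in sign to its test (upward at 0.529 without ACS replicate 1), 0.209 for excitation-contraction coupling (0.0170 without ACS replicate 3, upward at 0.850 without replicate 1), 0.200 for glycolysis (0.0210 without ACS replicate 3, upward at 0.762 without replicate 1) and 0.443 for the myogenic list, whose mean of 0.03 was opposite in sign to its median and test. Among muscle genes, adjusted over the list alone, 2 slow fibre genes were lower, 1 fatty acid gene was higher and 3 lower, 1 myogenic gene was higher and 1 lower, and none passed in the others. The mitochondrially encoded list had a median of 2.08 and adjusted p = 0.0695 upward. Without ACS replicate 1, which held 43.4% mitochondrial counts, its median was -0.40 and its test was downward (adjusted p = 0.0297). It was upward without replicates 2 and 3 (adjusted p = 0.000499 and 0.0207). Without ACS replicate 1, 1 slow fibre gene was lower, 1 fatty acid gene higher and 1 lower, and 1 myogenic gene higher and 1 lower. Without replicate 2, 1 slow fibre and 1 myogenic gene were lower and no fatty acid gene passed. Without replicate 3, 1 mitochondrially encoded gene, 1 fatty acid gene and 1 myogenic gene were higher and 1 fatty acid and 1 myogenic gene lower. No member of these lists passed in edgeR without any 1 control library.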

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

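The quality weights and the joint removal of haemoglobin genes, mitochondrial genes and ACS replicate 1 were chosen after seeing the data. All 533 called genes kept their sign under every alternative that tested them. Their groups were fully separated and at least 2-fold apart, so this was largely set by their selection and is no separate support. Of them 518 were shared with the calls under DESeq2 size factors, 526 under DESeq2 and 320 under limma-voom. The 2-fold limit removed none. The alternatives planned for a series with FPKM alone (pseudocount, value filter, centring, limma without trend) were not run, since counts were used, and 16 pairs of a named gene and an alternative gave no value because the gene was not tested there. Where a result crossed the threshold or turned its sign, the cause was not tested. Same-numbered libraries' deviations from their group means correlated at -0.0629, 0.0105 and 0.0397, and those of other pairs at -0.0686 to 0.0635. The values gave no sign of pairing by replicate number. With 3 libraries in each group and ACS replicate 1 apart from the others, they cannot exclude it. The replicate block gave 442 higher and 63 lower genes, 395 of them shared, with a log2 fold change of 3.69 for Ptgs2 (now past the threshold), adjusted p = 0.837 for the endothelial list (turned downward) and 0 list entries lower against 2. Depth limits the folds of Cxcl6, Mmp3, Csf3 and Trem1, which had 0 to 3 control counts. DESeq2 gave no adjusted p for 4055 genes, Ptgs2, Fosl1 and Trem1 among them, and the cause was not tested. The other named genes lost their call 90 times over the alternatives that kept all libraries or dropped more than 1, and 182 times when 1 library was left out. List member counts moved by over 1.5 times 114 and 85 times.

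Leaving out each library in turn gave 0 to 1286 higher and 0 to 398 lower genes, 0 to 110 list entries higher (53 with all libraries) and 0 to 5 lower, and 3 to 5 lists downward. The log2 fold change was 0.93 to 1.37 for Acsl4, 2.31 to 4.82 for Ptgs2, -0.41 to 0.36 for Myh1, -0.37 to 0.21 for Ryr1, -0.60 to 0.095 for Aldoa, -0.57 to 1.00 for Mt-co1, -1.12 to 0.0341 for Cd4 and -0.34 to 0.0331 for Abcc9. Set tests gave adjusted p from 0.00792 to 0.529 for necroptosis, 0.0425 to 0.231 for heat shock, 0.107 to 0.985 for fast fibre, 0.0170 to 0.850 for excitation-contraction coupling and 0.0210 to 0.762 for glycolysis. They gave 0.000499 to 0.0840 for mitochondrially encoded, 0.124 to 0.991 for endothelial, 0.0198 to 0.11 for smooth muscle and 0.0125 to 0.881 for the Schwann cell, adipocyte and tendon list.

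DESeq2 gave 1320 higher and 429 lower genes, 103 and 10 list entries, and a log2 fold change of 1.19 for Acsl4 (now past the threshold). Its set tests gave adjusted p = 0.0146 for heat shock, 0.00170 for mitochondrially encoded, 0.0194 for smooth muscle and 0.818 for lymphocyte (turned upward). Limma-voom gave 262 higher genes and 29 list entries, and set tests of 0.0906 for necroptosis, 0.0641 for apoptosis, 0.0453 for smooth muscle and 0.969 for endothelial (turned). Limma on FPKM gave 249 higher and 268 lower genes and 4 list entries lower, with Myh1 at -0.31 and Mt-co1 at -0.11 (turned). Its set tests gave 0.0294 for mitochondrially encoded, 0.0427 for smooth muscle, and 0.981 for both endothelial and myogenic lists (turned).

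With no filter 755 genes were higher and 153 lower, with 91 list entries higher and Ptgs2 at 4.26 (now past the threshold). Set tests gave 0.0438 for mitochondrially encoded, 0.0201 for smooth muscle, and 0.471 for lymphocyte and 0.845 for endothelial (both turned). The stricter filter put Ptgs2 at 4.42 (past the threshold) and necroptosis at 0.0560. Removing haemoglobin and mitochondrial genes gave 0.0499 for smooth muscle. Library totals gave 228 lower genes and 4 list entries lower, Ptgs2 at 3.85 (past the threshold) and Myh1 at -0.16 (turned). Set tests there gave 0.0123 for mitochondrially encoded, 0.0382 for smooth muscle and 0.799 for endothelial (turned).

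The term for "ji" libraries gave 248 higher and 32 lower genes, 0 list entries lower, Ptgs2 at 4.21 (past the threshold), and set tests of 0.0506 for necroptosis and 0.957 for endothelial (turned). Without both "ji" libraries there were 171 higher and 30 lower genes, 21 list entries higher and 0 lower, and Myh1 at -0.34 (turned). Set tests gave 0.0148 for excitation-contraction coupling, 0.0199 for glycolysis, 0.0263 for mitochondrially encoded and 0.0120 for the Schwann cell list, all now past the threshold. They gave 0.0551 for both fatty acid oxidation and fibroblast lists, no longer past it.

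Quality weights gave 1059 higher and 356 lower genes, 95 and 6 list entries, Acsl4 at 1.12 and Ptgs2 at 2.91 (both now past the threshold), and Myh1 at -0.0623 and Mt-co1 at -0.22 (turned). Set tests gave 0.0671 for ferroptosis drivers, 0.232 for necroptosis, 0.0989 for apoptosis, 0.0366 for smooth muscle and 0.845 for endothelial (turned). The joint removal gave 215 lower genes, 5 list entries lower, Ptgs2 at 2.32 (past the threshold), and Ryr1 at 0.21, Aldoa at 0.0993 and Abcc9 at 0.0376 (turned). Set tests gave 0.525 for necroptosis and for fast fibre, 0.846 for excitation-contraction coupling, 0.755 for glycolysis, 0.127 for endothelial and 0.0345 for smooth muscle. Of these, fast fibre, coupling, glycolysis and endothelial turned.

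With an estimated correlation every set test past the threshold was lost. The estimate was -0.0374 for hypoxia and -0.00592 for ferroptosis drivers, below the preset 0.01. For these lists the loss is therefore no sign of correlation among their genes. For hypoxia the unadjusted p of camera rose from 7.83e-05 to 0.0133 although its estimate was the lower. The setting also has few degrees of freedom with 6 libraries. For the other lists the loss alone thus cannot tell correlation from low power. Adjusted p was 0.260 for both ferroptosis lists, oxidative stress, unfolded protein, hypoxia, cytokines, matrix, slow fibre, atrophy, neutrophil and fibroblast lists. It was 0.599 for necroptosis, 0.373 for apoptosis, 0.341 for immediate early, 0.535 for nuclear-encoded oxidative phosphorylation, 0.450 for fatty acid oxidation, 0.407 for macrophage and 0.301 for red cell lists. The fry test, which asks whether a list's genes move one way and compares them with no other genes, gave adjusted p = 0.00620 for hypoxia. It gave 0.0668 for ferroptosis drivers and 0.0634 for suppressors, oxidative stress, atrophy and fibroblast lists. It gave 0.0747 for unfolded protein, 0.0718 for slow fibre, 0.109 for cytokine, matrix and neutrophil lists, and 0.1248 for apoptosis and red cell lists. For necroptosis it was 0.347, for immediate early 0.135, for nuclear-encoded oxidative phosphorylation 0.196, for fatty acid oxidation 0.145 and for macrophage 0.205.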

Other observations

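The tests on mitochondrially encoded genes (except the one on gene length), on neutrophil markers and on regroupings of the libraries were chosen after the results were seen.

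Some genes of the circadian clock, from a list fixed before its values were looked at, also differed, while most did not pass. Those named were chosen after their values were seen. Nfil3, a repressor in the clock, rose from 30.4 to 268.5 CPM (log2 fold change 3.14, SE 0.590, adjusted p = 0.0310; 2.20 without ACS replicate 2), and Ciart, another repressor, from 3.31 to 20.6 CPM (2.63, SE 0.509, adjusted p = 0.0330; 3.24 without control replicate 3). Nr1d1, the nuclear receptor REV-ERB alpha, fell from 165 to 52.9 CPM (-1.64, SE 0.323, adjusted p = 0.0345; 0.0558 without ACS replicate 2), and none of these passed without any 1 control library. Of 4 genes that peak with Arntl 1 was higher, and of 10 genes of the opposite, Dbp arm 1 was higher and 1 lower. Arntl itself measured 32.2 and 75.8 CPM (adjusted p = 0.178; log2 fold change 1.23, or 0.53 without ACS replicate 2; adjusted p = 0.0284 without replicate 3) and Dbp 49.2 and 34.4 CPM (adjusted p = 0.683; log2 fold change -0.51, -1.35 without ACS replicate 3, and turned to 0.34 without control replicate 3).

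Mitochondrially encoded reads took 43.4% of the counts in ACS replicate 1. A uniform loss of nuclear RNA would raise all 13 genes by a single factor, but their log2 ratios to the control mean spanned 5.19, from 1.00 for Mt-nd6 to 6.19 for Mt-atp6 (chosen after their values were seen), against 2.23 and 1.03 in the other ACS libraries. Carried-over mitochondrial DNA would add equal FPKM to the 12 heavy-strand genes, but the added FPKM differed 102-fold, from 929 to 94400. The low end was Mt-nd3 alone, at 1625 FPKM in ACS replicate 1 against 461 to 995 in control. Mt-nd4 was next, at 12982 against 775 to 935 (both chosen after their values were seen). The 102-fold range among these 12 genes thus rests on 1 gene. Mt-nd6, left out of this test, measured 1724 FPKM in ACS replicate 1 against 1177, 1136 and 1613 in control. Double-stranded DNA would add the same FPKM there too. The values of Mt-nd3 and Mt-nd6 thus argue against carried-over DNA as the only source of the rise. A smaller part from such DNA is not excluded. RNA degradation acting on gene length stays open, since log2 ratios correlated with gene length at 0.143 across 12848 genes (Spearman; 0.0985 and -0.052 in the other ACS libraries), too weak to decide. A severe form of the injury in this rat is among the open explanations and was not tested, so the pattern may be technical or biological.

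The 9 neutrophil markers, none of them in another list, had 1 at 1 CPM or more in control muscle (1.17 for Csf3r, chosen after its values were seen, also the most abundant in ACS at 54.2 CPM) and a median log2 fold change of 5.70, or 4.24 without ACS replicate 1 and 6.64 without control replicate 3. The filter had kept these 9 of 15 markers, and with no filter the median over 13 was 5.41. Blood retained in the tissue, if its share of neutrophils stayed the same, would raise the 9 markers no more than haemoglobin. They exceeded the haemoglobin genes (median 2.58) by 3.12 (2.48 without ACS replicate 1). Their index relative to haemoglobin was higher in every ACS library (-7.51 to -5.91) than in every control (-10.5 to -8.88). A lower share of fibre RNA would raise all non-muscle markers alike, but the medians were -0.36 for smooth muscle and pericyte, 0.21 for endothelial, 1.18 for Schwann cell, adipocyte and tendon, 1.21 for fibroblast and 1.90 for macrophage markers (-0.33, -0.115, 0.23, 0.54 and 0.99 without ACS replicate 1). The neutrophil median exceeded the endothelial by 5.49 (4.35 without ACS replicate 1), the fibroblast by 4.49 (3.70) and the macrophage by 3.80 (3.25), so a lower fibre share alone falls short of the rise, though it may add to it. A candidate explanation, as a hypothesis, is neutrophils entering the injured muscle, which was not tested. Retained blood with a higher share of neutrophils, or neutrophil genes switched on in the blood, would look alike and were not tested.

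Control muscle was taken at 0 h and ACS muscle at 18 h, so another time of day may account for part of the differences. The Dbp arm had a median log2 fold change lower than the Arntl arm by 1.03 (difference -1.03), past the bound set for a clock shift, but from -2.15 without ACS replicate 3 to -0.51 without ACS replicate 1, on both sides of it. The index of the arms was -1.12, -1.90 and 0.92 in the ACS libraries and -0.61, 0.62 and 1.60 in control, so the groups overlapped. Time of day and injury cannot be told apart here, since control muscle at 18 h was not analysed here.

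The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 533 changed genes and 1 split, the real one, gave as many. The highest count in another split was 0 in edgeR, with 170 to 696 genes at an unadjusted p under 0.05 against 3024 in the real grouping. Every other split mixes control and ACS libraries in both of its groups. A difference between the real groups then widens the spread within them, so low counts were likely in advance. The counts therefore do not decide whether chance accounts for the real grouping.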
